A study of Mus musculus with 2 samples.

How the data were processed

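The data are 2 single-colour (Cy3) Agilent mouse arrays, 1 per tumour, on 1 slide and 1 scan, so slide and scan date could not be tested as batches. Per the labels' protocols, total RNA was extracted with Trizol and 1.0 µg of it was labelled with the Quick Amp kit. The deposited intensity values (processed signal, mean signal and local background) were written by Agilent Feature Extraction, version 9.1.3.1 per the file headers and version 8 per the submitters' processing notes. Per the file headers, spatial and multiplicative detrending within the array and surrogates for low values were switched on for the processed signal intensity. No scaling between arrays was recorded. The deposited value table was identical to the processed signal intensity at every spot, on a linear, uncentred scale, with column medians of 63.3 and 67.5. The file of tumour 1 held values with at most 3 significant digits, and 47 of its spots had gene names that differ from those in the file of tumour 2, so names were taken from the latter. No column of values was left without a sample.

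Each array holds 45018 spots, of which 43379 are not controls. They represent 41174 probes, 245 of them printed 10 times. Accessions of 22944 probes (55.7%) matched the table of RefSeq genes of GRCm38.p6, which was used for names only, and 5139 of these received another symbol than in the file. Other probes kept the name in the file. The probes represent 28785 genes or transcripts, 17975 with a gene symbol. No genome build is given in the sources used here, so no coordinates are stated. Of the 506 genes in the 48 fixed lists, 6 were not found on the array under the listed names.

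Depth on an array is signal over background. Of the non-control spots, 27014 (62.3%) in tumour 1 and 28680 (66.1%) in tumour 2 were well above background. The 75th percentile of the processed signal was 894.5 and 947.8. Array 2 had 4 saturated spots and array 1 none. On array 2, 11 spots had a local background above 100, up to 65421.

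The main value was log2 of the processed signal minus the array's 75th percentile over non-control spots. Non-uniform and population-outlier spots were dropped, and spots of a probe were averaged. A probe was detected when at least 50% of its remaining spots were well above background, and a gene when any of its probes was detected on both arrays. The difference of a gene was the median over its detected, unsaturated probes. Without spots near flags, 338 of the 3440 genes with several detected probes had probes whose differences lay at least 2-fold apart. There are no groups to compare, so no test was run. Levels are mean ± SD of 2 tumours, and the standard deviation of repeat spots gives the technical error of a spot within an array, not between arrays. The median of a list with at least 3 detected genes was placed among 10000 random lists of the same size, matched on mean level in 20 bins. Genes above background on 1 array only received a lower bound.

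The named genes followed a rule set before the data were examined. It allowed the text to name the first 4 members of each list, list members at least 2-fold apart, the 12 largest differences in each direction among genes with a proper symbol whose probes went the same way, and the 6 largest bounds in each direction. Not every gene it allows is named, and the bounds towards tumour 2 were left out of the text after the data were seen. The same rule was applied again without spots near flags and to the lower rows. Alternatives were normexp background correction (offset 50), quantile and loess scaling (span 0.3), the median of detected probes as scale, the unscaled value table, other detection calls, no filter or the brighter 50% of detected probes, the brightest probe of a gene, and leaving out each tumour. After seeing the data 3 further alternatives were added: leaving out spots within 2 rows and columns of an outlier flag of array 1 or of a spot with high background on array 2, using only the rows below the flagged area, and fitting normexp without the 11 spots of high background.

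R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy, pandas and scipy were used. The procedure was tested on simulated data made from array 2 with spot noise of 0.2 (log2), for the comparison of tumour 2 with tumour 1 away from flags over 14720 genes. Of 100 genes changed 4-fold, 100% were called at least 2-fold apart, and of 100 genes changed 2-fold, 44% were, with a median recovered difference of 0.96. Of the unchanged genes 1 was called. Both simulated arrays came from array 2 and shared its detection calls, so they held no lost signal and no technical difference between arrays. The rate of false calls on the real arrays can therefore be higher. Of 40 unshifted lists 2 lay outside the interval.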

Results

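Gene expression was measured in 2 subcutaneous mouse tumours grown from RMS3, a mouse cell line that the labels call a PRMS line without spelling the abbreviation out. In each case 1000000 cells in 200 µl of buffer were injected into a male C57BL/6J mouse, and the tumour was taken 2 weeks later. The protocol text speaks of metastatic tumours at harvest, whereas every other label describes tumours at the injection site. Total RNA from each tumour was hybridised to its own single-colour array, so the data form 1 group of 2 tumours with no untreated, uninjected or cultured control. The labels give no purpose beyond this description. The comparisons are therefore which genes were above background in both tumours and how far the tumours differed from each other. With 1 tumour on each side of a difference there is no replicate check and no p-value, and the number of arrays limits the precision. The names tumour 1 and tumour 2 carry no order. Levels are log2 signals relative to the array's 75th percentile, given as mean ± SD (n = 2), and are comparable between tumours but not between genes.

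The tumours carried transcripts of the skeletal muscle lineage, although not of every regulator in it. Of the 10 myogenic regulatory factors listed, 8 were well above background on both arrays, among them Myod1 (-5.42 ± 0.25), Myog (-2.18 ± 0.09), Myf6 (-2.79 ± 0.34) and Mef2c (-1.27 ± 0.03), transcription factors that drive muscle differentiation. The call for Myod1 was a weak one. Its level lay close to the lowest that counted as well above background, -5.79 on array 1 and -6.34 on array 2. Myf5, an early determination factor, was not well above background on either array. Of the 10 embryonic and neonatal muscle genes 9 were detected, including the developmental myosin heavy chains Myh3 (-1.60 ± 0.76) and Myh8 (2.01 in tumour 1 and 2.99 in tumour 2). Of the 22 genes of adult muscle fibres 19 were detected, for example the fast myosin Myh4 (1.55 ± 0.84) and the muscle creatine kinase Ckm (-4.55 ± 0.36). Pax7, the marker of satellite cells, was not above background on either array, while its relative Pax3 was detected. Among 14 genes tied to rhabdomyosarcoma, a tumour of the muscle lineage, 11 were detected, with the growth factor Igf2 at 1.35 ± 0.35 (0.29 ± 0.43 with all spots) and the receptor Fgfr4 at -4.66 ± 0.16.

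All 11 tumour suppressors and oncogenes listed were detected in both tumours. Trp53 lay at -0.99 ± 0.15, Cdkn2a, which encodes the inhibitors p16 and p19, at 0.98 ± 0.01 and Myc at 3.03 ± 0.53. All 16 listed target genes of p53 were detected as well, including the cell cycle inhibitor Cdkn1a (2.55 ± 0.11, and 1.75 ± 1.15 with all spots) and the apoptosis gene Bax (2.11 ± 0.23). Proliferation genes were detected in 19 of 20 cases, with Mki67 at 0.82 ± 0.05 and Top2a at -2.87 ± 0.06 (-1.59 ± 0.07 with all spots). All 16 fibrillar collagen and matrix genes were detected, Col1a1 at 3.49 ± 0.24 (1.60 ± 0.30 with all spots) and Col1a2 at 6.32 ± 0.04, and all 14 oxidative phosphorylation genes. For Top2a, Col1a1 and Igf2 fewer probes counted away from flags. Their 2 levels thus rest on different sets of probes and do not show the effect of the flags alone. The hypoxia response genes were detected in 13 of 14 cases, with the glucose transporter Slc2a1 at 6.81 ± 0.02 and Vegfa at 4.16 ± 0.03. For Vegfa this SD understates the gap, as the median difference of its 3 probes was 0.31 (tumour 2 minus tumour 1). As a reference, 69.4% of the 17975 genes with a symbol on the array were detected on both arrays.

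Transcripts of other cell types were present to different extents. All 12 endothelial markers and all 10 fibroblast markers were detected, as were 12 of 13 macrophage markers, including Adgre1 (-0.84 ± 0.45), Cd68 (-0.18 ± 0.15) and the complement gene C1qa (0.01 ± 0.04). T cell markers were detected in 7 of 14 cases: Cd3e was above background on both arrays, and Cd8a, Cd4 and Foxp3 were above it on neither. Of the 11 markers of natural killer and cytotoxic cells 5 were detected, and of the 10 B and plasma cell markers 2. All 7 genes of MHC class II antigen presentation were detected. None of the 7 hepatocyte markers on the array was detected on both arrays, and of the 8 lung epithelial markers 1, the club cell gene Scgb1a1 (-5.49 ± 0.38), which also lay close to the lowest level called. The Y-linked genes Ddx3y, Eif2s3y and Kdm5d were detected in both tumours, while Uty and Xist, the X inactivation transcript, were each above background in tumour 1 alone, Xist in neither tumour away from flags.

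The difference between the tumours was disturbed by the surface of array 1. Its scanner file marks 1071 spots as non-uniform, against 43 on array 2, and its outlier-flagged spots lie in bands. The lower rows are taken here as those below row 338 of 532, a limit set so that 95% of these flagged spots lie above it, with 63.5% of all spots. Unflagged spots beside these bands had lost signal too. Of 1590 repeat spots, flagged ones included, 158 on array 1 lay more than 2-fold below the median of their probe. Of these 93.0% were flagged or within 2 rows and columns of a flag, against 28.3% of all repeat spots. On array 2, 1 repeat spot lay that far below. The 10 spots of Cdkn2a ranged from 0.80 to 0.96 on array 2 and from -3.57 to 1.23 on array 1, whereas the 7 of them away from flags spanned 1.09 to 1.23 on array 1. Among unflagged spots the standard deviation of a repeat spot was 0.61 on array 1 and 0.13 on array 2 (log2), and on array 1 it was 0.23 once the neighbourhood of the flags was left out. Levels and differences of named genes are therefore given without spots near flags, a setting chosen after seeing the data, and the value from all spots is added where it differs by more than 1.5-fold beyond the general shift. Where a gene kept fewer probes away from flags, the 2 values rest on different sets of probes.

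**Figure D1:**
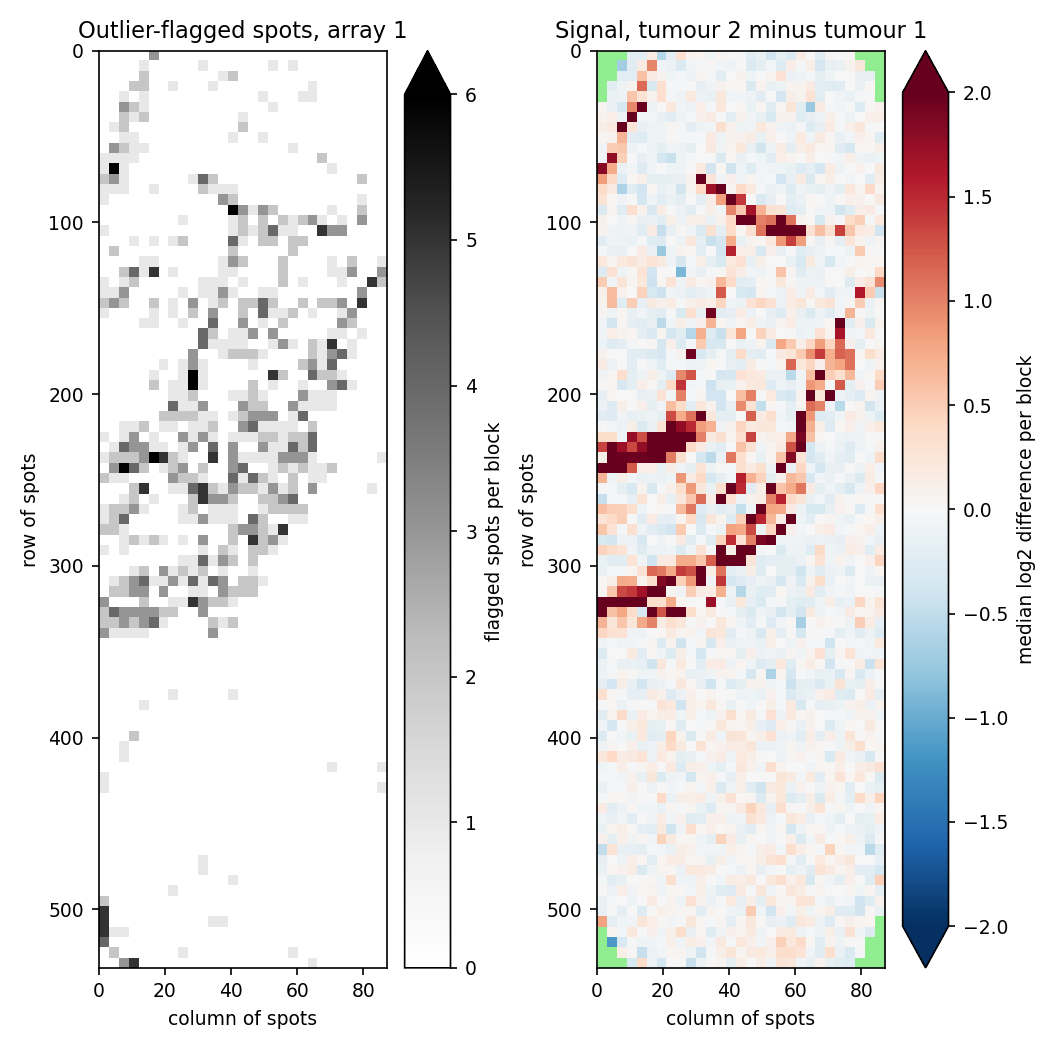
Position on the array of the outlier-flagged spots of array 1 (left, spots per block of 6 rows by 3 columns) and of the median log2 difference in signal, tumour 2 minus tumour 1, of spots above background on both arrays, relative to the median of all such spots (right; green marks blocks with no such spot). The dark red bands, where tumour 1's signal was low, run through the flagged areas and stop at about the row below which few spots are flagged.

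Across all 16812 genes detected on both arrays the tumours correlated with Pearson r = 0.960 and Spearman rho = 0.954, values across genes, which are not independent replicates. The median difference was -0.21 (log2, tumour 2 minus tumour 1), and it was -0.01 without spots near flags. In the setting fixed before the data were examined 1153 genes were at least 2-fold higher in tumour 1 and 849 in tumour 2. Without spots near flags these counts were 539 and 361 of 13945 genes, and in the lower rows alone 279 and 148 of 8042. Of the 332 genes at least 2-fold higher in tumour 2 that were still measured away from flags, 208 remained so, and of the 962 at least 2-fold higher in tumour 1, 521. Leaving spots out also moved the scale. Genes with no spot near a flag shifted towards tumour 2, for example Cxcl13 from -5.18 to -4.96 and Kcna7 from -2.62 to -2.40. This shift alone takes genes just beyond 2-fold out of the tumour 1 count, so its losses do not count bad spots. The share of these genes that were higher in tumour 2 was 42.4% in the fixed setting and 61.8% after loess scaling. Away from flags the differences had a standard deviation of 0.55. Control probes for added RNA (spike-ins) differed there by -1.27 to 0.79 (log2, array 2 minus array 1). Most of them were higher on array 2 by a similar amount, 0.60 to 0.79. Of those lower on array 2, the probes at -0.50 and -0.56 lay below the lowest level called well above background, and the probe at -1.27 did not. The slope that the scanner software fitted to the spike-ins was 1.08 on array 1 and 0.82 on array 2. Technical differences between the arrays can thus exceed the error of a spot within an array and reach the size of list medians given below.

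**Figure D2:**
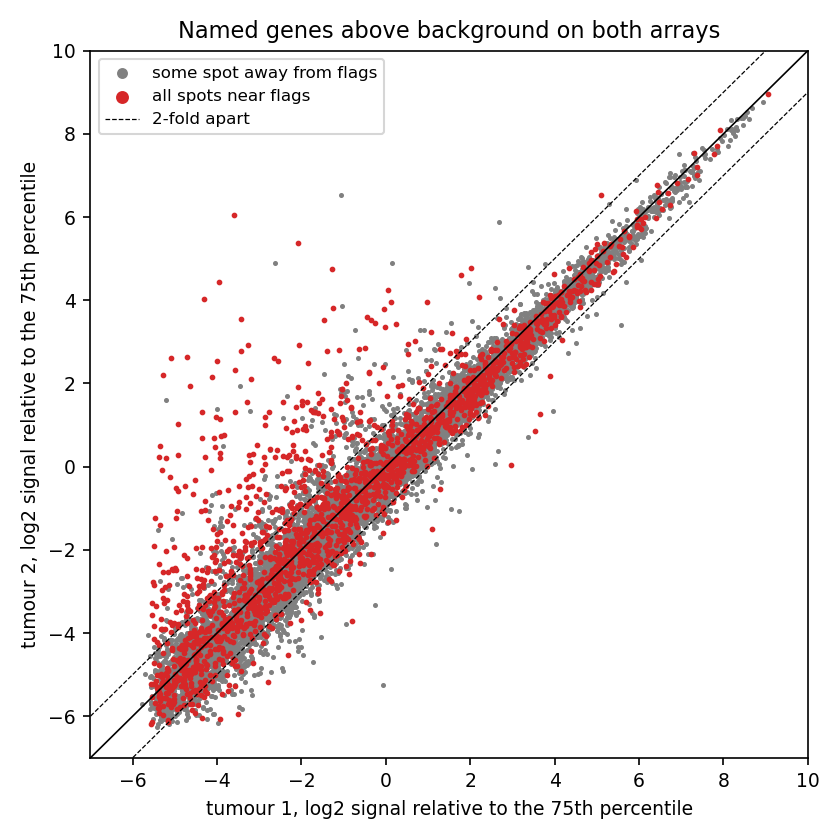
Log2 signal of each named gene detected on both arrays in tumour 1 (x axis) and tumour 2 (y axis), relative to the 75th percentile of the array, all spots used. Red points are genes with all spots near a flag of array 1, and most of the points far above the upper dashed line, which marks a 2-fold difference, are red.

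Muscle genes were higher in tumour 2. Of the 6 embryonic and neonatal muscle genes measured away from flags 5 were higher in tumour 2, Myh3 by 1.07 (2.10-fold), Myh8 by 0.97 and the fetal acetylcholine receptor subunit Chrng by 0.87. The median of the list was 0.92, against -0.33 to 0.40 for the central 95% of 10000 random lists of the same size and mean level. Adult fibre genes were higher in tumour 2 in 15 of 17 cases, with a median of 0.46 against -0.19 to 0.27, Myh4 by 1.19 and Myh2 by 0.46. Under the planned normexp background correction, which could not be fitted properly on array 2, the adult list lay level with matched genes and the embryonic list inside the random interval. The imprinted growth-related transcript H19 was 1.12 higher in tumour 2, without a value in the lower rows to check it. The regulators did not go with them: 6 of 8 myogenic regulatory factors were higher in tumour 1, with a median of -0.37 against -0.32 to 0.34, a direction that turned under the planned normexp correction. This list lay inside the random interval after quantile scaling, in the normexp refit and in the lower rows. When only the brighter probes were kept, 5 embryonic genes remained and their median lay below that of matched genes, inside the random interval.

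Keratinocyte, erythroid and neutrophil markers were also higher in tumour 2. The basal keratins Krt5 and Krt14 differed most, by 3.55 (11.7-fold) and 3.64 (12.5-fold), Krt14 without a spot in the lower rows to check it. In tumour 1 Krt5 lay at -5.22, close to the lowest level called on array 1 (-5.79), so its fold value is uncertain. The 5 measured keratinocyte markers had a median of 0.81 against -0.38 to 0.43, except under the planned normexp correction, where they lay slightly below matched genes. All 4 erythroid markers were higher, the haemoglobin chain Hba-a1 by 0.89 and the haem synthesis enzyme Alas2 by 0.98 (median 0.94 against -0.36 to 0.44). All 4 neutrophil markers were higher, S100a8 by 0.47 and S100a9 by 0.36 (median 0.47 against -0.35 to 0.44). Of 10 immediate early genes, which respond within minutes to stimuli, 7 were higher in tumour 2, Egr1 by 1.65 (3.14-fold) and Jun by 0.43 (median 0.33 against -0.17 to 0.26). Egr1 had no value in the lower rows to check it. Unfolded protein response genes were higher in 7 of 8 cases, Ddit3 by 0.59 (median 0.37 against -0.17 to 0.27). In the lower rows the erythroid list stayed outside the random interval, the immediate early genes (0.37 against -0.26 to 0.40) and unfolded protein response genes (0.36 against -0.27 to 0.40) lay inside it, and too few keratinocyte and neutrophil markers were measured there. Under the planned normexp correction the erythroid, neutrophil and unfolded protein response lists lay inside the interval.

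MHC class II genes were higher in tumour 1. The invariant chain Cd74 lay at -0.13 in tumour 1 and -1.29 in tumour 2, a difference of -1.16 (2.23-fold). H2-Aa differed by -1.13, H2-Eb1 by -1.14 and H2-DMb1 by -0.95, and 5 of 6 measured members were higher in tumour 1. The median of the list was -1.04 against -0.43 to 0.43 in random lists, except under the planned normexp correction, where the list lay level with matched genes. Interferon-stimulated genes were higher in tumour 1 in 13 of 15 cases, with a median of -0.49 against -0.32 to 0.28. Examples are Ifit1 (-0.91), Usp18 (-0.91), Oas1a (-0.84) and Isg15 (-0.49). An exception is Irf7 (0.66), which in tumour 1 lay close to the lowest level called (-5.53 against -5.79). In the lower rows the MHC class II list kept its place (-1.06 against -0.42 to 0.44), whereas the interferon-stimulated genes lay inside the interval (-0.39 against -0.48 to 0.47), as they did under the planned normexp correction.

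Fibroblast and endothelial markers and some chemokines were higher in tumour 1 too. The fibroblast markers had a median of -0.55 against -0.26 to 0.38, with the proteoglycan Dcn at -1.12 and the microfibril gene Mfap5 at -1.95 (3.86-fold). With all spots their median did not leave the random interval, and under the planned normexp correction it turned. In the lower rows it was -0.84 against -0.31 to 0.40, over 4 genes. Endothelial markers were higher in tumour 1 in 9 of 11 cases, with a median of -0.33 against -0.24 to 0.31, Kdr at -0.45 and the sialomucin Emcn at -0.97. In the lower rows the endothelial list lay inside the interval (-0.27 against -0.37 to 0.42), with 4 of 7 higher in tumour 1. Cytokines and chemokines had a median of -0.19 against -0.17 to 0.24, with Ccl8 at -1.46 (2.74-fold) and Cxcl5 at -1.59. Schwann cell markers had a median of -0.63 against -0.56 to 0.54 over 4 genes. The chemokine list and the Schwann cell list lay inside the random interval with all spots, and in the normexp refit the Schwann cell list lay level with matched genes. In the lower rows the chemokine list lay outside the interval (-0.25 against -0.20 to 0.30).

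**Figure D3:**
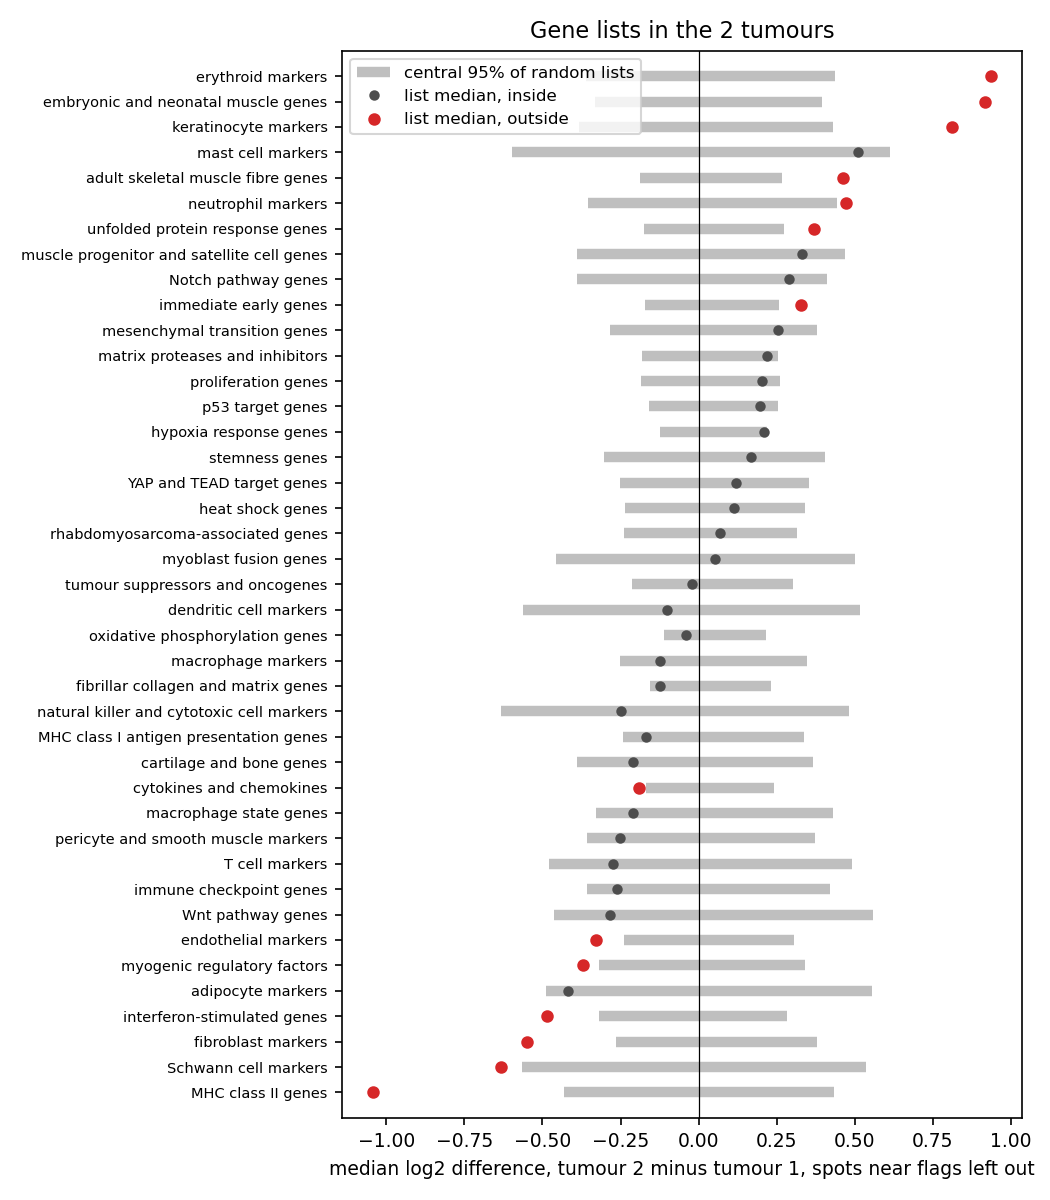
Median log2 difference of each gene list, tumour 2 minus tumour 1, without spots near flags (points), and the central 95% of 10000 random lists matched on size and mean level (grey bars). Of 41 lists with enough genes 14 lay outside the bar (red), from -1.04 for MHC class II genes to 0.94 for erythroid markers.

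In all, 15 of 43 testable lists lay outside the central 95% of random lists with all spots and 14 of 41 without spots near flags, and 11 were outside in both in the same direction. Chance would put about 2 lists outside in either case, and since members of a list tend to vary together these percentiles only describe these 2 arrays. Lists inside the interval without spots near flags included the proliferation genes (median 0.20 against -0.18 to 0.26), p53 targets (0.20 against -0.16 to 0.26), hypoxia response (0.21 against -0.12 to 0.22), oxidative phosphorylation (-0.04 against -0.11 to 0.22), collagen and matrix genes (-0.12 against -0.16 to 0.23) and macrophage markers (-0.12 against -0.25 to 0.35). In the setting fixed beforehand, with all spots, the macrophage markers lay just outside (-0.42 against -0.42 to 0.17), with 11 of 12 higher in tumour 1. In the lower rows the p53 targets (0.34 against -0.19 to 0.32) and the collagen and matrix genes (-0.22 against -0.20 to 0.29) lay outside it. Single members of such lists still differed by at least 2-fold, such as Mycn (-1.15), the matrix gene Postn (-1.31), the urokinase gene Plau (1.26), the scavenger receptor Marco (-1.22) and the adipocyte marker Cfd (-1.69). Mdm2 was 0.94 higher in tumour 2 and Cdkn1a 0.16 higher, against 1.67 and 1.62 with all spots. With all spots Acta1 (5.68), Psmb10 (5.09) and Cxcl2 (4.33) were far higher in tumour 2 but had no spot away from flags, and Myh1 (4.88) was above background in tumour 2 alone away from flags.

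**Figure D4:**
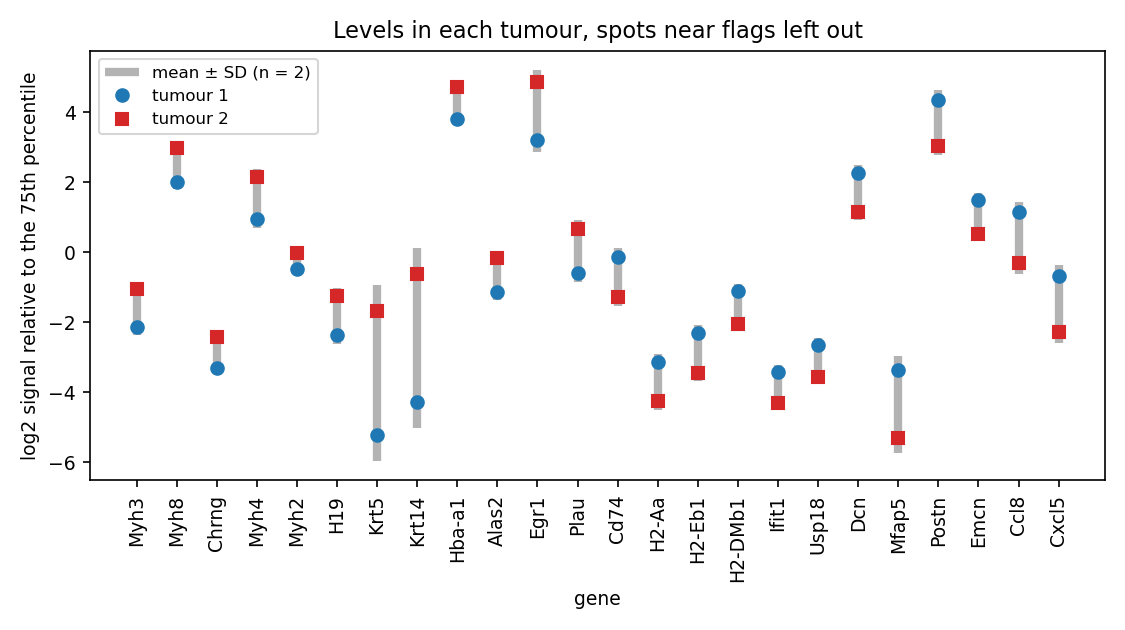
Log2 signal relative to the array's 75th percentile of 24 genes named in the text in tumour 1 (circles) and tumour 2 (squares), without spots near flags, with the mean and SD of the 2 tumours (grey bars). The first 12 genes were higher in tumour 2 and the last 12 higher in tumour 1; levels of different genes are not comparable.

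The largest single differences towards tumour 1 were led by Cxcl13, a chemokine that attracts B cells, at -0.22 in tumour 1 and -5.17 in tumour 2 (-4.96, 31.1-fold). Of the 12 genes with the largest difference in that direction 7 were olfactory receptors, headed by Olfr661 (-2.84) and Olfr1198 (-2.81). The potassium channel gene Kcna7 (-2.40), the flagellin receptor Tlr5 (-2.34), the adrenergic receptor Adrb1 (-2.34) and Adamts15 (-2.32) made up the rest with Cxcl13. Towards tumour 2, 10 of the 12 largest differences with all spots belonged to genes with every spot near a flag, among them Phlda1 (9.65), Nop2 (8.40) and Polr1c (8.36). Without those spots the largest values were those of Rpl30 (7.80) and Bok (7.77), whose spots lie in a gap between flagged areas. The blocks of spots around them, their own spots included, had median differences of 4.29 and 7.75, the latter close to the value of Bok itself. In the same rows the blocks to either side had medians of 3.26 and 3.37 for Bok and 3.37 and 0.35 for Rpl30. The values of both genes are therefore read as lost signal on array 1 and not as differences between the tumours. Of the 12 genes in that setting 2 were measured in the lower rows, where Krt5 differed by 3.53 and Cttnbp2nl by 0.21. In the lower rows the next genes after Krt5 were Usf1 (2.88) and Aldh3b1 (2.74). Of genes above background in tumour 1 alone, Sh3gl2 was at least 11.6-fold, Plg at least 8.05-fold and Cd70 at least 6.28-fold higher there, although the other probes of Sh3gl2 and Plg were not well above background on either array. Each bound is the brighter value over the lowest signal that counted as well above background on the other array. No bound is given towards tumour 2, where lost signal on array 1 would produce one.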

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

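The planned normexp correction did not work on array 2. With its 11 spots of high local background in the fit, the median corrected intensity was 1262.6 on array 2 and 135.7 on array 1, and without them 137.2 on array 2. Its values are printed as they came out, and the refit, the setting without spots near flags and the lower rows were chosen after seeing the data. Under the planned fit r was 0.904, 7357 genes were at least 2-fold higher in tumour 2 and 3 lists lay outside the random interval, against 592 genes and 13 lists in the refit.

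Genes at least 2-fold higher in tumour 1 numbered 664 after loess, 2353 without a filter on dim probes, 228 in the brighter 50% of detected probes, 539 without spots near flags, 394 in the normexp refit and 279 in the lower rows. Those higher in tumour 2 numbered 1798 without the filter, 334 in the brighter 50%, 361 without spots near flags and 148 in the lower rows. Detected genes numbered 8042 in the lower rows, which hold fewer genes. The pooled spot standard deviation of 0.42 was 0.18 without spots near flags, 0.10 in the lower rows and 0.13 to 0.61 with 1 tumour left out. The share of 2-fold genes that were higher in tumour 2 was 61.8% after loess, 84.2% under the planned normexp fit, 60.0% in the refit and 59.4% in the brighter 50%, against 42.4%. Quantile scaling, the median scale, the value table and the brightest probe kept both 2-fold counts within 1.5 times. Of the lists outside the random interval with all spots, directions turned under the planned normexp fit, relative to matched genes, for the myogenic regulatory factors (0.23), MHC class II genes (0.024), keratinocyte markers (-0.039) and Y-linked genes (0.18), and the embryonic and neonatal muscle genes turned (-0.16) in the brighter 50%. The fibroblast markers, inside the random interval with all spots but outside it away from flags and in the lower rows, turned under the planned fit as well (0.45). So did some lists inside the interval. Single genes that turned under the planned fit, none of them in the refit, were Adamts15 (0.79), Cfd (0.85), H2-Aa (1.79), H2-DMb1 (0.27), H2-Eb1 (1.46), Ibsp (2.31), Icos (2.27), Ifit1 (1.93), Il7r (1.70), Itgax (0.91), Kdm5d (2.15), Klrd1 (1.98), Marco (1.955), Mfap5 (2.01), Mycn (1.95), Oas1a (1.85), Tlr5 (1.01) and Usp18 (1.43). No paired analysis was possible because there is 1 group.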

Other observations

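Several groups of genes were not compared above. Without spots near flags, the Notch pathway genes had a median difference of 0.29 (tumour 2 minus tumour 1) against -0.39 to 0.41 in random lists, the Wnt pathway genes -0.28 against -0.46 to 0.56, and the YAP and TEAD targets 0.12 against -0.25 to 0.35. Among the last, the LIM protein gene Ajuba stood apart at 2.10 (4.27-fold), on 1 probe and without a value in the lower rows to check it. Only 2 of 7 Hedgehog pathway genes were detected on both arrays. MHC class I genes had a median of -0.17 against -0.24 to 0.34, immune checkpoint genes -0.26 against -0.36 to 0.42, T cell markers -0.27 against -0.48 to 0.49, natural killer and cytotoxic cell markers -0.25 against -0.63 to 0.48, and dendritic cell markers -0.10 against -0.56 to 0.52. Within these, Il7r (-1.08), Icos (-1.21), Klrd1 (-1.61) and Itgax (-1.04) were at least 2-fold higher in tumour 1. Macrophage state genes had a median of -0.21 against -0.33 to 0.43, mast cell markers 0.51 against -0.60 to 0.61, and adipocyte markers -0.42 against -0.49 to 0.55. In the setting fixed beforehand, with all spots, 3 lists not described above lay outside the interval towards tumour 1: the Wnt pathway genes just so (-0.59 against -0.59 to 0.44), the adipocyte markers (-0.76 against -0.68 to 0.54) and the Y-linked genes (-0.78 against -0.77 to 0.72).

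Other lists lay inside the random interval as well. Medians were 0.33 against -0.39 to 0.47 for muscle progenitor genes, 0.05 against -0.46 to 0.50 for myoblast fusion genes, 0.07 against -0.24 to 0.32 for rhabdomyosarcoma-associated genes, -0.02 against -0.21 to 0.30 for tumour suppressors and oncogenes, 0.22 against -0.18 to 0.25 for matrix proteases and inhibitors, 0.26 against -0.28 to 0.38 for mesenchymal transition genes and -0.25 against -0.36 to 0.37 for pericyte and smooth muscle markers. In the lower rows the pericyte and smooth muscle markers lay outside on the other side (0.91 against -0.41 to 0.52, 3 of 4 higher in tumour 2), and the rhabdomyosarcoma-associated genes lay outside too (0.50 against -0.37 to 0.41). Away from flags medians were -0.21 against -0.39 to 0.37 for cartilage and bone genes, 0.11 against -0.24 to 0.34 for heat shock genes and 0.17 against -0.30 to 0.40 for stemness genes. Among the cartilage and bone genes Ibsp differed by -1.62, but in tumour 2 it lay close to the lowest level called (-5.88 against -6.34). Away from flags too few B cell, lymphatic endothelial and Y-linked genes were measured to place these lists among random lists.

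All tests in the remaining paragraphs were chosen after the result was seen, and the single group of the design offers no biological explanation to test. The first pattern is the excess of probes at least 4-fold higher in tumour 2. Of 753 such spots 87.3% lay within 2 rows and columns of an outlier flag of array 1, against 23.2% of all spots detected on both arrays, which is consistent with local loss of signal on array 1. A bright blemish on array 2 is argued against as far as the local background shows one. Its 11 spots of high background lay in rows 516 to 520, and 0 of the 753 spots lay within 2 spots of them. Of the 753 spots 99.3% lay in rows up to 338. A blemish that left the local background unchanged was not tested.

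The second pattern is that muscle genes were higher in tumour 2 and MHC class II genes in tumour 1. Loss of signal on array 1 is argued against for the embryonic muscle genes, which away from flags still lay 0.89 above matched genes. Some lost spots remained in that setting. In the lower rows, where few spots were flagged, the median of these genes was 0.90 against -0.32 to 0.45 in random lists. Such loss would lower tumour 1, so the MHC class II genes, higher there (-1.03 away from flags), do not test it. Scaling is argued against in the scalings that worked: the gap between the medians of both lists was 1.97 after quantile scaling, 1.90 after loess and 1.23 with normexp refitted without the high-background spots, against a spread of 0.58. The planned normexp fit gave a gap of -1.18, and it is set aside here only because of the failure described for array 2, which was recognised after this value was seen. Fewer tumour cells in one piece stays open. Erythroid and fibroblast markers moved apart by 1.49, but these 2 lists were picked after their positions were seen, so the gap cannot decide. Relative to matched genes, fibroblast (-0.59), endothelial (-0.34) and macrophage markers (-0.16) lay opposite to the muscle genes. Erythroid (0.90), keratinocyte (0.80) and neutrophil markers (0.43) lay on the same side as the muscle genes. Host muscle in the piece of tumour 2 stays open too, since adult fibre genes spread over 1.30 and the tumour line could express them itself.

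The third pattern is the number of olfactory receptors among the largest differences towards tumour 1: 13 of the top 50 named genes without spots near flags, where 0.30 would be expected from their share of detected genes. Genomic DNA in tumour 1's RNA stays open: of the 46 olfactory receptor genes above background on 1 array alone 28.3% were so on array 1, against 33.0% of all such genes, while 16 were at least 2-fold higher in tumour 1 and 1 in tumour 2, and the 7 detected vomeronasal receptors, too few to decide, had a median of 0.18 relative to all genes with 0 at least 2-fold higher in tumour 1. Cross-hybridisation of these probes was not tested.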
